A study of Homo sapiens with 2 samples.

How the data were processed

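Single-nucleus RNA-seq was deposited for 2 libraries of human trophoblast organoids, 1 made from the trophoblast stem cell line CT27 and 1 from CT29. Per the labels, nuclei were captured with 10x Genomics 3' chemistry, kit version 3.1, and read as pairs of 150 bp. The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, made by the authors with Cell Ranger 8.0.1 on GRCh38, per the submitters' processing notes. The annotation release is not given in the sources used here. The matrices hold 10880 barcodes for CT27 and 10691 for CT29, where the labels' protocols state about 10000 nuclei per library. They had no further normalization.

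Genes of the Y chromosome and the XIST locus, 105 in all, were left out of every table, which left 36496 genes. Of these, 34511 matched GENCODE 29 by gene ID, the source of all coordinates (GRCh38). A nucleus was kept with at least 500 genes, at least 1000 UMIs and at most 5% mitochondrial UMIs. Doublets were scored with Scrublet in scanpy 1.11.5 for each library. The automatic threshold marked 0.0460% of CT27 and 0.00935% of CT29 barcodes and was taken not to have worked, so the top scores at 0.8% per 1000 barcodes were removed, 9.63% of CT27 and 8.73% of CT29 barcodes with ties. This left 5395 nuclei for CT27 and 4261 for CT29. Median depth among them was 1909 UMIs in CT27 and 6487 in CT29, so the libraries differed in depth after the filter. Over all barcodes the medians were 2766 and 2527, so this gap arose with the filters. The mitochondrial limit was exceeded by 38.1% of CT27 and 30.1% of CT29 barcodes. All shares of kept nuclei rest on this uneven removal. Counts were log-normalized and scaled within each library. Clusters came from 2000 variable genes, 30 components, 20 neighbours and the Leiden method (leidenalg 0.10.2) at resolution 0.6.

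The cell type markers were fixed before the data were examined, and the rule that turns them into cluster names was not. A marker counted when it reached 10 CPM and 2 times a reference level in each library with at least 20 nuclei of the cluster, and a name needed 3 markers. Earlier versions set markers against all other nuclei pooled, then against the median over clusters, then against that median with clusters of mixed markers left unnamed. The last of these was tested on simulated data and failed: simulated cytotrophoblast nuclei of CT27 were left without their name. Then 8 rules were compared on simulated nuclei alone, by the mean percent of nuclei given the right name, and the best was used. It scored 84.8%, the earlier rule 83.1% and the lowest 76.5%. In this rule the leading class is that with the largest share of its markers counted. A cluster stays unnamed if another class has 3 markers and at least 0.75 of the leading share. In all 8 rules it also stays unnamed if its top 10 genes by fold hold more markers of another class than of the leading one. The same holds if its median depth is more than 3 times below the library's median and no marker of the leading class is among them. The top-gene criterion left cluster 1, with 57.6% of CT27 and 30.9% of CT29 nuclei, unnamed: 14 of 24 proliferating and 13 of 34 syncytiotrophoblast markers counted in it. The simulated profiles came from clusters as named by the earlier rule, so this comparison is not independent of it.

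The simulated recovery, run on 36496 genes, limits what the shares can show. Extravillous and syncytiotrophoblast nuclei were named at 100% in both lines. Each simulated class used the same profile for both lines, summed over CT27 and CT29. A difference between lines within a class was thus not simulated. The 100% therefore does not show that extravillous-like shares can be compared between lines. With each class at its own depths, 33.3% of simulated cytotrophoblast nuclei were recovered in CT27 and 64.6% in CT29. With depths shared between classes these values were 45.7% and 76.7%. Recovery of proliferating nuclei ran from 49.7% to 91.0%.

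With 1 library per line there is no test and no p-value. The labelled batch is 1 for CT27 and 2 for CT29, so line and batch cannot be separated. Counts were summed over nuclei and given as CPM, counts scaled to the library total. Ratios of CPM carry conditional exact binomial 95% intervals and shares of nuclei carry exact Clopper-Pearson 95% intervals, and both cover counting error only. A library under 3 UMIs was set to 3 in a ratio. Gene lists were described by the percentile of their median log2 ratio among 10000 random lists of the same size, matched on mean expression in 20 bins. Shares of nuclei with a UMI were taken after thinning each nucleus to 2000 UMIs. Named genes are the 12 highest and 12 lowest ratios at 50 CPM or more in the higher line, for each class and for all nuclei, up to 4 members of each list by size of the ratio at 10 CPM or more, and preset markers. Mitochondrial and ribosomal protein genes and clone names were not eligible.

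The ratio steps were tested on simulated data with 200 changed genes. For all nuclei, on 10279 genes, 100% of genes changed 3-fold and 0% of genes changed 1.5-fold came out at 2-fold or more, and the intervals held the true ratio for 95.5% of genes. For cytotrophoblast-like nuclei, on 10242 genes, the interval coverage was 95.3%. Of 40 simulated unchanged lists, 1 fell outside the central 95% for all nuclei and 3 did for cytotrophoblast-like nuclei. Counts were drawn independently for each gene and the lists were random genes. The simulation therefore checks the computation only. It does not show how often real lists of co-regulated genes fall outside, or cover library differences beyond counting error.

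Alternatives were other nucleus filters, doublets kept, resolutions of 0.3 and 1.0, genes scaled over both libraries together, each library clustered alone, edgeR's TMM (4.0.16) and DESeq2's size factors (1.42.0) as scales, the mean of each nucleus's CPM, other expression minimums, other thinning and 10 bins. A minimum of 4000 UMIs and the other 7 naming rules were added after seeing the data, as were all alternatives for syncytiotrophoblast-like and proliferating-like shares and for list medians in extravillous-like nuclei, among them cluster 3 alone.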

Results

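Organoids of 2 human trophoblast stem cell lines, CT27 and CT29, were compared after the same culture. They were grown for 11 days in rotation, a form of simulated microgravity, and then for 14 days in Matrigel in medium that directs cells towards extravillous trophoblast, the invasive cells of the placenta. Nuclear RNA was counted in 1 library per line. The CT27 matrix held 87944860 UMIs in 10880 barcodes and the CT29 matrix 84592091 UMIs in 10691 barcodes. No value below has a replicate check, and line and labelled batch coincide. Intervals in brackets are 95% and cover counting error only.

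Many barcodes were shallow. Of the deposited barcodes, 41.7% of CT27 and 44.2% of CT29 held fewer than 2000 UMIs, and ribosomal protein genes took a median of 6.78% and 9.29% of UMIs in them. In barcodes of 10000 UMIs or more the medians were 1.46% and 1.61%. The filters and doublet removal kept 49.6% of CT27 and 39.9% of CT29 barcodes and turned the order of median depth. After filtering, 1 unnamed cluster of low depth (medians of 1237 and 1366 UMIs) held 57.6% of CT27 and 30.9% of CT29 nuclei. Its top genes by fold included CGA and CGB3, subunits of chorionic gonadotropin, and the cytoplasmic housekeeping transcript GAPDH.

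The first question was which trophoblast types each line gave. Nuclei like extravillous trophoblast, with markers such as ITGA1, NOTUM and HTRA4, made up 4.10% (3.58 to 4.66) of kept CT27 nuclei and 18.4% (17.2 to 19.6) of kept CT29 nuclei. Different clusters held them: in CT27 clusters 3, 11 and 12 held 106, 22 and 93 nuclei, and in CT29 they held 668, 115 and 0. These clusters counted 9, 11 and 10 of 22 extravillous markers. These shares leave out unnamed cluster 5, with 300 CT27 and 287 CT29 nuclei. It counted 11 of 22 extravillous markers, but also 12 syncytiotrophoblast and 9 proliferating markers. Unnamed cluster 4, with 286 and 480 nuclei, was closest to extravillous trophoblast but counted only 1 of its markers. The size of the difference in share varied between settings. With each library clustered alone the shares were 14.4% and 15.9%, and with genes scaled over both libraries together they were 8.38% and 57.3%; with no filter on nuclei they were 1.41% and 3.57%. At 4000 UMIs or more they were 18.0% and 34.2%, a ratio of 1.90 against 4.49 in the main setting. Without clusters, 17 of 19 measured extravillous markers were above 0 in log2 ratio of CT29 over CT27 in summed counts of all nuclei. Their median was 0.66, at the 100th percentile of matched lists, and 6 were 2-fold or more higher in CT29. With the mean of each nucleus's CPM the median was 0.38, at the 99.8th percentile. These markers were also higher in CT29 inside other classes, with medians of 0.56 in cytotrophoblast-like, 0.56 in syncytiotrophoblast-like and 0.92 in proliferating-like nuclei. The shift was therefore not confined to the extravillous-like class. It does not speak against a larger share. Free RNA from extravillous nuclei could raise these markers in other classes, which was not tested. HLA-G, the class I molecule of invasive trophoblast, had a log2 ratio of 0.88, and NOTUM, a secreted WNT inhibitor, had 1.26. HLA-G counted as a marker in cluster 11 but not in clusters 3 and 12. After thinning it had a UMI in 59.2% of CT27 and 70.4% of CT29 extravillous-like nuclei. Over all nuclei these values were 50.0% and 64.0%, and in cytotrophoblast-like nuclei 27.9% and 46.3%. HLA-G thus set the class apart only weakly from all nuclei.

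Nuclei like cytotrophoblast, the progenitor layer, with markers such as TP63, ITGB4 and MET, made up 12.4% (11.5 to 13.3) of CT27 and 19.4% (18.2 to 20.6) of CT29. These shares cannot be compared between lines. Simulated cytotrophoblast nuclei were recovered unevenly, at 33.3% in CT27 and 64.6% in CT29, and the direction turned under 3 of 14 alternatives. Over all nuclei the cytotrophoblast markers ran the other way from these shares, with 2 of 15 above 0 and a median log2 ratio of -0.70 at the 0th percentile of matched lists. Inside the cytotrophoblast-like class their median was 0.084. In other classes the median stayed below matched lists, at -0.57 in syncytiotrophoblast-like, -0.44 in extravillous-like and -0.43 in proliferating-like nuclei. Syncytiotrophoblast-like nuclei, the hormone-secreting fused layer, made up 4.87% (4.32 to 5.48) and 5.02% (4.39 to 5.72). CT27 was higher with the stricter filter, at 9.002% against 5.96%, and at 4000 UMIs or more, at 7.84% against 4.79%. Over all nuclei 12 of 29 syncytiotrophoblast markers were above 0, with a median of -0.37 at the 0.200th percentile. Inside 3 classes it ran the other way, at 0.44 in syncytiotrophoblast-like, 0.44 in extravillous-like and 0.55 in proliferating-like nuclei. It was -0.029 in cytotrophoblast-like nuclei. The extravillous-like value did not hold in cluster 3 alone, where the median was -0.14 at the 39.65th percentile, with 9 of 20 markers above 0. Unnamed clusters held 74.9% of CT27 and 50.0% of CT29 nuclei.

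**Figure D1:**
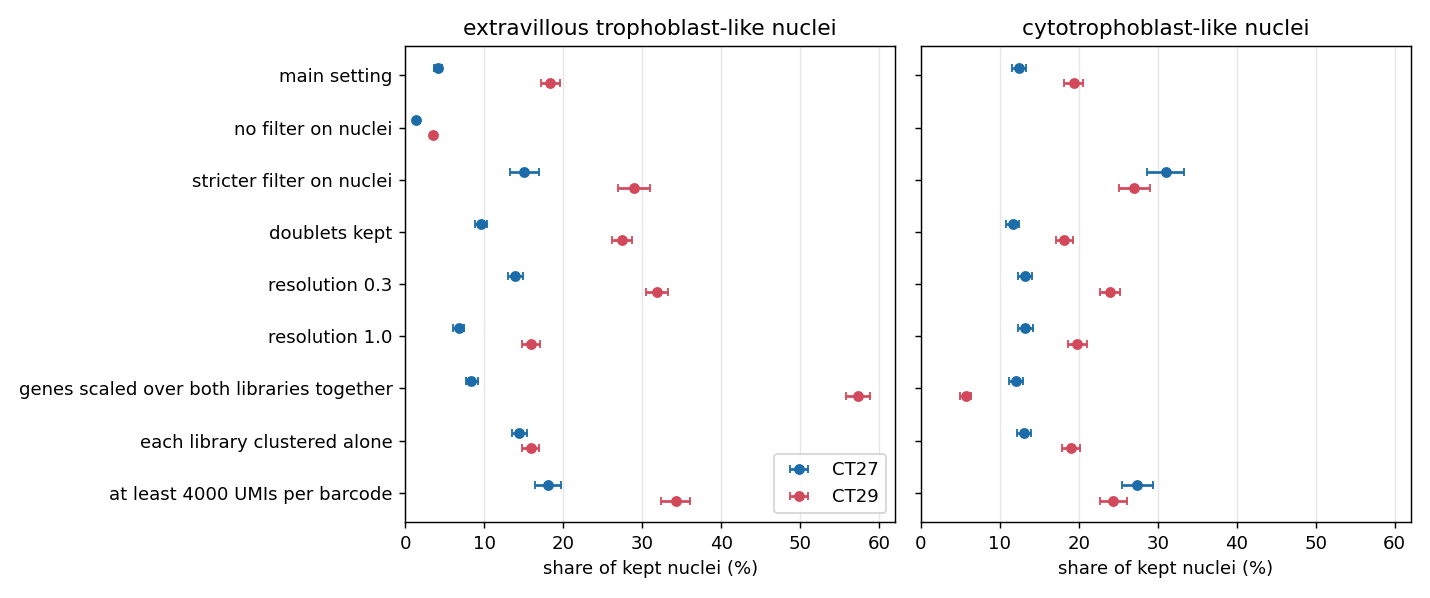
Share of kept nuclei (%, horizontal axis) named extravillous trophoblast-like (left) and cytotrophoblast-like (right) in CT27 (blue) and CT29 (red) under the main setting and 8 alternatives, with exact 95% intervals. The extravillous shares are 4.10% and 18.4% in the main setting; the gap is smallest with each library clustered alone (14.4% and 15.9%) and widest with genes scaled together (8.38% and 57.3%), and the cytotrophoblast shares change order between settings.

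Proliferating-like nuclei made up 3.30% (2.84 to 3.81) of CT27 and 7.02% (6.27 to 7.83) of CT29. The order turned under 3 of 15 alternatives, of which 7 were naming rules that left both shares unchanged. Simulated recovery was also uneven, so these shares cannot be compared between lines. Counted without clusters after thinning to 2000 UMIs, 9.26% (8.18 to 10.4) of 2623 CT27 nuclei and 8.42% (7.48 to 9.45) of 3158 CT29 nuclei had a UMI of MKI67 or TOP2A, genes of dividing cells. Thinning left out 2772 CT27 and 1103 CT29 nuclei, and the unthinned shares were 21.4% and 20.8%. In syncytiotrophoblast-like nuclei, which do not divide, the thinned shares were 2.74% and 2.48%, at median depths of 13016 and 9310 UMIs among thinned nuclei against 10856 and 9752.5 for all. The thinned difference of -0.84 points (-2.33 to 0.62) included 0. With thinning to 1000 UMIs it was -2.52 (-3.60 to -1.43) and with no filter -1.28 (-2.55 to -0.014).

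Between the lines, 1103 of 10279 genes with at least 10 CPM in the higher line were 2-fold or more apart over all nuclei, 631 higher in CT29 and 472 higher in CT27. The widest gaps were in genes close to silent in 1 line. FAM155A (chromosome 13, 107163510 to 107866735) had a log2 ratio of -7.30 (-7.90 to -6.76), and GABRG3 (chromosome 15, 26971282 to 27541991), a GABA receptor subunit, had 6.83 (6.36 to 7.35). GPR39, a zinc-sensing receptor, was at -4.76 and ROR2, a WNT5A receptor, at -3.20. Both are also leading genes of cluster 7, which held 6.41% of CT27 and 1.10% of CT29 nuclei. HPGD, which breaks down prostaglandins, was at 2.64, BST2, an antiviral membrane protein, at 3.17, and HLA-B at 4.59 (4.41 to 4.76).

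Within cytotrophoblast-like nuclei, 669 in CT27 (clusters 2, 9 and 14) and 825 in CT29 (clusters 2 and 9), 807 of 10242 genes were 2-fold or more apart, 631 higher in CT29 and 176 higher in CT27. This split depended on scaling: it was 433 and 231 with TMM and 346 and 272 with DESeq2 size factors. FAM155A stood at -7.55 (-9.17 to -6.32), MALRD1 at -6.25 (-6.98 to -5.60) and the dipeptidyl peptidase-like DPP10 at -3.71. GABRG3 stood at 7.25 (5.88 to 9.13), HLA-B at 3.90 (3.47 to 4.37) and CSH1, placental lactogen, at 2.17 (2.13 to 2.21). CSH1 shares near-identical sequence with CSH2, so its counts are uncertain.

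Interferon response genes were higher in CT29 in each class compared. In extravillous trophoblast-like nuclei 14 of 16 measured members were 2-fold or more higher in CT29 and 0 were 2-fold lower, with a median log2 ratio of 1.48 at the 100th percentile of matched lists. IFIT1 stood at 3.34 (3.05 to 3.65), IFIT2 at 3.32 (2.78 to 3.92), the antiviral GTPase MX1 at 2.83 (2.64 to 3.04) and IFIT3 at 2.58 (2.31 to 2.85). The class differed in make-up: cluster 12, which CT29 lacks, gave 60.6% of its CT27 UMIs, and cluster 11, the highest of the 3 in summed CPM of the list, gave 5.44% in CT27 and 18.7% in CT29. In cluster 3 alone the median was 0.97, at the 100th percentile, and 7 of 15 members were 2-fold or more higher in CT29 and 0 lower. There IFIT1 stood at 2.83 (2.35 to 3.36) and MX1 at 2.55 (2.22 to 2.90). In cytotrophoblast-like nuclei the median was 0.50 and 6 of 17 members were 2-fold higher, led by IFI27 at 2.22 and MX1 at 2.00. In syncytiotrophoblast-like nuclei the median was 0.95, with 7 of 17. After thinning, MX1 had a UMI in 9.48% (5.89 to 14.3) of CT27 and 28.9% (25.7 to 32.2) of CT29 extravillous-like nuclei, and in 33.9% and 75.5% unthinned. In cluster 3 alone the thinned shares were 11.5% (5.86 to 19.6) and 25.7% (22.5 to 29.2).

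**Figure D2:**
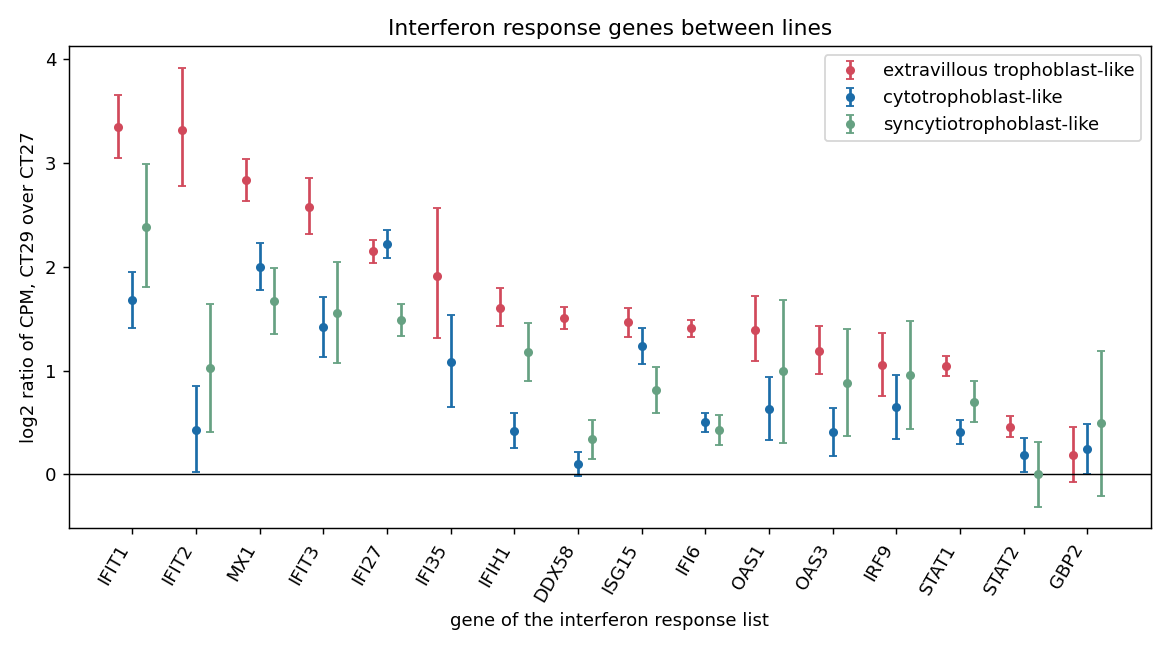
Log2 ratio of CPM, CT29 over CT27 (vertical axis), for the 16 interferon response genes measured in extravillous trophoblast-like nuclei (red), with cytotrophoblast-like (blue) and syncytiotrophoblast-like nuclei (green) and 95% counting intervals. In the extravillous-like class all 16 points lie above 0, from IFIT1 at 3.34 downwards.

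Antigen presentation genes were also higher in CT29. In extravillous-like nuclei 12 of 12 measured members were above 0, with a median of 0.92 at the 100th percentile. Of these, 5 were 2-fold or more higher in CT29 and 7 were within 2-fold. In cluster 3 alone 3 of 11 were 2-fold or more higher. In the class HLA-B stood at 4.76 (4.34 to 5.22) and PSMB8, a subunit of the immunoproteasome, at 2.43 (1.81 to 3.12). HLA genes are polymorphic and alike, and read assignment can depend on a line's alleles. Matrix and invasion genes had a median of 0.35 in this class at the 100th percentile, but 16 of 18 were within 2-fold; TIMP1, a protease inhibitor, stood at 1.84 and SERPINE1, another, at -1.06. Hypoxia response genes had a median of -0.34 at the 0.370th percentile; 13 of 15 were within 2-fold, NDRG1 stood at -1.41 and CA12 at 1.12. In cluster 3 alone the medians of these 3 lists were 0.65, 0.23 and -0.57. Over all nuclei the hypoxia median was -0.43, with VEGFA at -1.28 and the glucose transporter SLC2A1 at -1.06, but in cytotrophoblast-like nuclei it was 0.07 at the 85.4th percentile.

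The last comparison set extravillous-like against cytotrophoblast-like nuclei within each line. Markers of both classes served to name the clusters, so their contrast is no finding; 15 of 19 extravillous markers were 2-fold or more higher in the extravillous-like class in both lines. Some preset lists share members with the markers, and members that served for naming are left out here. Circularity remains, because clusters were formed jointly in both lines on variable genes, which may include list members. The counts below only describe these clusters, with no share over all genes beside them. Of 14 other matrix and invasion genes, 7 were higher by 2-fold in both lines and 3 were lower. Antigen presentation genes were higher for 5 of 8 and lower for 0. Hypoxia genes were lower for 8 of 17 and higher for 0, with VEGFA at -2.10 in CT27 and -2.79 in CT29. YAP and TEAD targets were lower for 6 of 11 and higher for 1. With cluster 3 alone in place of the class, matrix genes were higher for 6 and lower for 2, antigen presentation genes higher for 5, hypoxia genes lower for 8, and YAP and TEAD targets lower for 5 and higher for 1.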

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

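The tests in this part were chosen after the result was seen, except that of line against labelled batch. Genes eligible to be named were searched for opposite directions in the 2 lines between extravillous-like and cytotrophoblast-like nuclei. A gene needed 10 CPM in the higher class and a 2-fold difference, in each line. Among members of the preset lists, 1 gene, IFIT2, met these limits. Its log2 ratio was -1.44 (-2.10 to -0.82) in CT27 and 1.45 (1.15 to 1.75) in CT29, a gap of 2.89; this difference was not tested. In cluster 3 alone the ratios were -1.52 (-2.69 to -0.53), from 9 CT27 UMIs, and 1.26 (0.96 to 1.58). Over all eligible genes, 3 met these limits. IFIT2 was not alone in direction: the 16 measured interferon response genes had a median of -0.29 in CT27 and 0.74 in CT29 between these classes.

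The higher extravillous-like share in CT29 was weighed against the clustering. Among barcodes of at least 4000 UMIs the shares differed by 16.2 points (13.7 to 18.7), which argues against dilution by shallow barcodes as the whole cause. The ratio of the shares was 1.90 there against 4.49 in the main setting, so dilution may account for part of it. With each library clustered alone the difference was 1.43 points (-0.01 to 2.88). In that setting variable genes were also chosen per library, and a marker had to count in only 1 library. Joint clustering or joint naming may therefore account for most of the difference, and these cannot be told apart. The extravillous markers' median log2 ratio of 0.66 over all nuclei, against -0.29 to 0.15 for the central 95% of matched lists, is consistent with more extravillous RNA in the CT29 library, whatever the clusters, and does not say in how many nuclei. With the mean of each nucleus's CPM this median was 0.38. It was 0.56, 0.56 and 0.92 inside the cytotrophoblast-like, syncytiotrophoblast-like and proliferating-like classes, so the shift was not confined to the extravillous-like class. These values cannot decide on a larger share. Free RNA from extravillous nuclei could raise the markers in other classes, which was not tested. Line and labelled batch, with 1 library per line, cannot be told apart.

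The higher interferon response in CT29 was weighed against free RNA. Free RNA would weigh most on shallow nuclei, so the difference in summed CPM of the list would be at most as large in deeper nuclei; a bound of 2 set earlier was too wide. It was 2.70 (2.55 to 2.85) times as large in the deeper extravillous-like as in the cytotrophoblast-like nuclei, and 1.86 (1.74 to 1.98) times in cluster 3 alone, which run against free RNA. Yet it was 0.61 (0.57 to 0.65) times as large in cluster 3 as in cluster 1, the shallowest, at 4018 CPM in CT29 against 2092 in CT27, which goes with it. Cluster 3 stood at 2095 CPM in CT29 against 919 in CT27. As a ratio of the lines the gap was thus larger in cluster 3, so this comparison depends on the scale. Free RNA stays open. If the different clusters in the extravillous-like class were the whole cause, no difference would remain inside 1 shared cluster. In cluster 3 the median log2 ratio was 0.97, against -0.34 to 0.097 for matched lists and 1.48 in the class. This argues against the mix of clusters as the whole cause. It does not hold the state of nuclei fixed: in cluster 3 cytotrophoblast markers had a median of -0.93 and extravillous markers 0.47. A different make-up within cluster 3 stays open. More interferon-lambda nuclei in CT29 could be a source. Cluster 13, where these genes lead in CT27, differed by -0.173 points (-0.41 to 0.067), too few nuclei to decide. Not all its nuclei carried these genes: IFNL1 had a UMI in 3 CT27 and 2 CT29 nuclei of the cluster. Its class, cell column trophoblast-like, differed by -1.03 points (-1.66 to -0.50) at 4000 UMIs or more. With each library clustered alone the class differed by -0.50 points (-0.73 to -0.32). Whether interferon-lambda genes lead in the clusters of those settings was not checked. Line and labelled batch, with 1 library per line, cannot be told apart, and a difference between the lines stays untested.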

How the results depend on the processing

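No paired analysis was possible because each line has 1 library and no result comes from a test. Differences in share are CT29 minus CT27 in percentage points. The extravillous-like difference of 14.3 points stayed above 0 under 15 of 15 alternatives, by 1.43 to 48.9. Of these, 7 were naming rules on the same clusters, which were unlikely to turn its sign. With each library clustered alone the interval, -0.01 to 2.88, included 0. The difference was still 14.3 under naming rules 1, 3 and 4. It was 2.15 with no filter on nuclei, 17.8 with doublets kept, 17.9 at resolution 0.3, 9.12 at resolution 1.0, 48.9 with genes scaled over both libraries together, 1.43 with each library clustered alone, 16.2 at 4000 UMIs or more and 11.99 under each of the 4 naming rules that set markers against all other nuclei. The cytotrophoblast-like difference of 6.96 points turned to -3.98 with the stricter filter, -6.31 with genes scaled together and -3.05 at 4000 UMIs or more; it was 10.8 at resolution 0.3 and 4.40 under 3 other naming rules, and no cluster took the name without a filter, so that the largest-class count has no value there either. The thinned proliferation difference of -0.84 turned to 0.0717 with the stricter filter and 0.61 at 4000 UMIs or more, and was -2.52 (-3.60 to -1.43) with thinning to 1000 UMIs and -1.28 (-2.55 to -0.014) with no filter. The syncytiotrophoblast-like difference of 0.15 points turned to -0.76 with no filter, -3.04 with the stricter filter, -0.23 with each library clustered alone and -3.05 at 4000 UMIs or more. Under naming rules 7 and 8 it was 1.32 (0.064 to 2.60), from 10.4% and 11.8%. The proliferating-like difference of 3.72 points turned to -12.3 with the stricter filter, -1.82 at resolution 1.0 and -1.67 with genes scaled together. It was 2.21 with no filter and 7.02 with each library clustered alone, where no CT27 cluster took the name. Counts of genes 2-fold apart were 5124 for all nuclei and 3074 for cytotrophoblast-like nuclei with no minimum beyond 10 UMIs, and 412 and 240 at 50 CPM or more, because these rules change how many genes enter; other settings stayed within 1.5 times. TMM and DESeq2 moved the cytotrophoblast-like ratios by -0.12 and -0.18 in log2. The pregnancy-specific glycoprotein median for all nuclei turned to -0.25 at 50 CPM or more and the pan-trophoblast median in cytotrophoblast-like nuclei to -0.022 with DESeq2 size factors. The cause of these changes was not tested, except where the number of genes explains a count. In the extravillous-like class the medians of 4 lists kept their sign under 6 alternatives. For interferon response, 1.48 was 0.97 in cluster 3 alone and 1.03 with each library clustered alone. For hypoxia response, -0.34 was -0.57 and -1.11. The 4000 UMI minimum, the naming rules, these alternatives for the class and the alternatives for syncytiotrophoblast-like and proliferating-like shares were chosen after seeing the data. Depth limits the smallest classes: cluster 13 held 22 and 10 nuclei.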

Other observations

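The test for another cell type was set before its value was seen, and the doublet test after. A cluster of 22 CT27 and 10 CT29 nuclei was named cell column trophoblast-like from 5 of 10 markers. Its top 10 genes by fold were VDR, IFIT2, CCL5, PDE7B, PMAIP1, IFNL2, IFNL1, IFNL3, OASL and FTCD. Its markers and top genes were judged in CT27 nuclei alone, because CT29 had too few nuclei for the naming rule. PMAIP1 had a UMI in 20 CT27 and 6 CT29 nuclei, IFIT2 in 14 and 4, CCL5 in 8 and 1 and OASL in 5 and 0. The cluster was chosen after its values were seen, and no list was tested for enrichment in it. Over the cluster's nuclei of both lines IFIT2 reached 2521 CPM, against 54.3 in the highest other cluster. The interferon-lambda signal itself came from few nuclei: IFNL1 had 29 UMIs in 3 CT27 and 2 CT29 nuclei. The cluster also counted 9 syncytiotrophoblast and 4 proliferating markers. Its median doublet score lay at the 35.6th percentile of kept nuclei in CT27 and the 77.4th in CT29, so doublets of other clusters stay open. The pan-trophoblast genes had a median log2 ratio of -0.49 to the median cluster, from -1.75 for TFAP2C to 0.74 for KRT18. By the limits set beforehand this goes against another cell type than trophoblast. Free trophoblast RNA could supply these genes in any droplet, which was not tested, so the value cannot decide.

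PECAM1, an adhesion molecule of endothelium, was lower in CT29 over all nuclei with a log2 ratio of -2.90 (-3.11 to -2.69). Of 8 vascular adhesion genes measured, 2 were 2-fold or more higher in CT29 and 2 lower, with a median inside the central 95% of matched lists. Of 15 imprinted genes measured in extravillous-like nuclei, 2 were 2-fold or more higher in CT29 and 2 lower. Their median of -0.26 lay inside the central 95% of matched lists, but in cluster 3 alone it was -0.45, at the 0.170th percentile. IGF2, a fetal growth factor, stood at 2.71 (2.32 to 3.13), SGCE at 1.13 (0.93 to 1.35) and MEST at -1.24 (-1.50 to -0.97). MEG8 had 87 UMIs in CT27 and 2 in CT29, an interval of -10.1 to -5.10, but 1 and 2 in cluster 3, so nearly all of its CT27 UMIs lay in the other clusters of the class.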
